A study of Mus musculus with 20 samples.

How the data were processed

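The samples were 20 RNA-seq libraries from C57BL/6 mouse material: 14 libraries of myeloid cells isolated from bone marrow or spleen by depletion of CD3e-positive cells, and 6 libraries of the melanoma lines B16F10 and YUMM3.3. Groups were taken from the tissue, disease state and cell type labels. The labels do not tie libraries to animals or say whether marrow and spleen came from the same animals, so nothing here was paired.

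Per the submitters' processing notes, the submitters used FastQC 0.11.8, STAR 2.7.1a, featureCounts 1.6.0 and DESeq2 1.22.2 with the mm10 build. The role of each tool is not given in the sources used here. The files analysed were 14 gene set enrichment reports, a pair for each of 7 comparisons, with 1 report for each direction. Per the file headers, each deposited row gives a gene set, its size, its enrichment score (ES), its normalised enrichment score (NES), the rank at the maximum and the leading edge. The p-values in the deposited reports, per the file headers, are a nominal p, a false discovery rate q (FDR q) and a family-wise p (FWER p). An NES is an ES divided by the mean ES of permuted data for the set, so that sets of different sizes can be compared. No per-library values and no member genes were analysed here, so no SD between replicates, no fold change per gene and no test of a single gene could be computed, and the gene lists prepared for that purpose were not used. The sequencing depth of the libraries is unknown here, and no value was weighted by depth. The reference annotation was not used here.

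The reports list sets of both directions separately, and the sign of NES in them did not follow 1 convention across comparisons. Each myeloid report was read as listing the sets higher in its first-named group. Both cell line reports name YUMM3.3 first, so they were read by their labels, up as higher in YUMM3.3 and down as higher in B16F10. The deposited NES of the cell line sets named below was positive for up and negative for down. Every signed value below was set so that positive means higher in the first-named group of the comparison. The reading was checked by correlating NES of B16F10 against YUMM3.3 with the difference of the NES of each tumour against healthy. Pearson's r was 0.720 in bone marrow and 0.767 in spleen. Turning B16F10 against healthy alone gave 0.493 and -0.139, turning YUMM3.3 against healthy alone gave -0.493 and 0.139, and turning the tumour comparison alone gave -0.720 and -0.767. This check would not detect all 3 comparisons of a tissue being turned together, and it does not cover the cell lines.

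How the authors permuted the data is not given in the sources used here. The smallest nonzero nominal p in the deposited tables was 0.00103, while relabelling libraries could not give less than 0.167 with 2 against 2, 0.1 with 3 against 2, or 0.05 with 3 against 3. The deposited p and q values therefore cannot rest on relabelled libraries and do not measure the spread between animals or cultures. The listed FWER p moved in steps of 0.001.

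A gene set counted as changed at a deposited FDR q below 0.05. Before the data were examined, 28 themes were fixed as patterns in set names, and 27 of them had at least 5 listed sets; the proteasome theme did not and was not tested. Results of 2 tested themes and of some sets are not reported here, though counts of themes include them. Names ending in DN were left out of themes and kept in the background. A set whose name matched several patterns counted in each of those themes. Each theme and direction was tested with a two-sided Fisher's exact test of its sets against all other listed sets, adjusted by Benjamini-Hochberg over themes and directions within the comparison, and called at an adjusted p below 0.05 with an odds ratio above 1. Gene sets share genes, so these p-values are too small, and they compare sets and not animals. Theme differences between tissues were tested as the mean NES in spleen minus that in bone marrow against 10000 random lists of as many sets matched on set size decile, two-sided, with Benjamini-Hochberg adjustment over 54 tests. The two-sided p doubled the smaller tail, and the smallest value it can give is 0.0002. That form replaced a distance from the random median after results had been seen, because NES has a peak on each side of 0, and the earlier form is kept among the alternatives.

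The sets named are, per comparison and direction, drawn from the 8 with the largest NES size past the threshold, at most 2 per first word of the name, and the leading set of each called theme. Chance agreement from shared healthy libraries was simulated 10 times per tissue with unchanged libraries of the real group sizes and random sets of the real sizes. The theme test and the random-list test were tested on simulated reports with the 3883 set names of B16F10 against healthy bone marrow. With 3 themes shifted by an NES of 1.5, Fisher's test called 60 of 60 shifted and 1 of 760 unshifted themes, and with no shift it called 0 of 1080. The random-list test on medians found 15 of 15 shifted themes, and its p was below 0.05 in 7 of 135 unshifted ones. Real sets overlap, which the simulation left out.

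Alternatives were other thresholds, set sizes of 25 to 200 genes, canonical pathways only, each source counted once, DN sets kept, median NES against random lists, ES in place of NES and unmatched random lists. Counting each source once kept a single set per source and combination of themes. A source with sets in different combinations of themes could therefore still enter a theme more than once. Analyses were run in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.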

Results

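Messenger RNA was sequenced from myeloid cells of healthy and melanoma-bearing C57BL/6 mice and from cultures of the melanoma lines B16F10 and YUMM3.3. B16F10 is a mouse melanoma line selected for metastasis, and YUMM3.3 is a line from a genetically engineered mouse melanoma. Bone marrow was represented by 3 libraries from healthy animals, 3 from B16F10-bearing animals and 2 from YUMM3.3-bearing animals. Spleen was represented by 2 libraries in each of the same conditions, and each cell line by 3 libraries. The design asks how myeloid expression differs between healthy and tumour-bearing animals, how the tumours differ in this respect, and how the lines themselves differ. The values analysed were the authors' gene set enrichment results for 7 comparisons. The myeloid comparisons each listed 3883 gene sets of 15 to 483 genes, and the cell line comparison listed 3871 sets of 15 to 500 genes. The depth of the libraries is unknown here. No spread between replicates could be computed, because the values are 1 per gene set and comparison, and the deposited q values do not measure that spread. Directions in the myeloid comparisons rest on reading each report as the sets higher in its first-named group. Those in the cell lines rest on the up and down labels of the reports. A joint reversal of a tissue's 3 comparisons, or of the cell lines, cannot be excluded from the files.

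**Figure D1:**
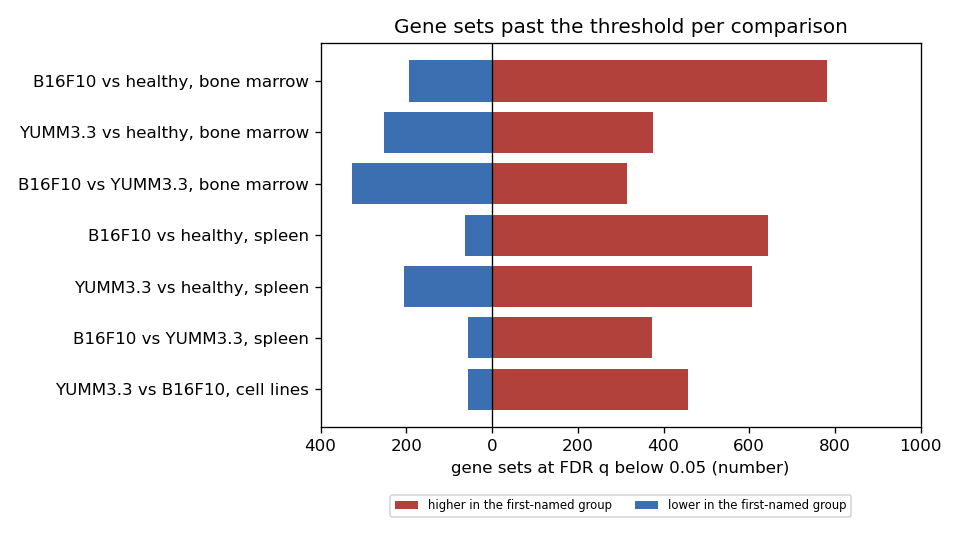
Number of gene sets at a deposited FDR q below 0.05 in each of the 7 comparisons, with bars to the right for sets higher in the first-named group and bars to the left for sets lower in it. The longest bar is 781 sets higher in B16F10-bearing than in healthy bone marrow, and the shortest are 57 sets, in B16F10 against YUMM3.3 spleen and in the cell lines.

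In bone marrow of B16F10-bearing animals, sets for translation, mitochondrial function, the cell cycle, interferon and inflammatory responses were higher than in healthy marrow, and sets for B cells and for hematopoietic stem and progenitor cells were lower. Of the 3883 sets, 781 were higher and 194 lower. The authors' deposited table listed ALTEMEIER_RESPONSE_TO_LPS_WITH_MECHANICAL_VENTILATION, a lung response to bacterial lipopolysaccharide, with the largest NES, 2.93, followed by REACTOME_TRANSLATION with 2.90. HESS_TARGETS_OF_HOXA9_AND_MEIS1_DN had an NES of 2.82 in the authors' deposited table, REACTOME_MITOCHONDRIAL_TRANSLATION 2.73 and SCHLOSSER_MYC_TARGETS_REPRESSED_BY_SERUM 2.66. Of 16 ribosome and translation sets, 14 were higher and 0 lower (Fisher's exact test, adjusted p = 3.48e-07). The cell cycle theme had 43 of 84 sets higher and 1 lower (adjusted p = 7.47e-09), and mitochondrial respiration had 14 of 20 higher and 0 lower (adjusted p = 2.48e-05). The mitochondrial theme took any set name containing MITOCHONDRI as well as respiration terms. Its leading set here, REACTOME_MITOCHONDRIAL_TRANSLATION, also counts in the ribosome and translation theme. Interferon sets were higher in 12 of 21 cases and lower in 0 (adjusted p = 0.00212), led in the authors' deposited table by ZHANG_INTERFERON_RESPONSE with an NES of 2.25. Inflammatory signalling had 25 of 68 sets higher and 0 lower (adjusted p = 0.00804). Hypoxia and glycolysis had 14 of 31 higher and 0 lower (adjusted p = 0.0123), and stress and unfolded protein had 5 of 6 higher and 0 lower (adjusted p = 0.00977). The authors' deposited table gave the leading hypoxia set, REACTOME_CELLULAR_RESPONSE_TO_HYPOXIA, an NES of 2.53. The leading cell cycle set, REACTOME_APC_C:CDH1_MEDIATED_DEGRADATION_OF_CDC20_AND_OTHER_APC_C:CDH1_TARGETED_PROTEINS_IN_LATE_MITOSIS_EARLY_G1, had an NES of 2.72 in the authors' deposited table. Genes shared between the leading sets of these themes could not be counted without member genes, so the calls may not be separate.

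Among the sets lower in B16F10-bearing marrow, the authors' deposited table gave HADDAD_B_LYMPHOCYTE_PROGENITOR the largest NES size, 2.74, with PASQUALUCCI_LYMPHOMA_BY_GC_STAGE_DN at 2.60 and KEGG_PRIMARY_IMMUNODEFICIENCY at 2.53. IVANOVA_HEMATOPOIESIS_STEM_CELL_LONG_TERM was also lower, with an NES size of 2.37 in the authors' deposited table. Hematopoietic stem and progenitor sets were lower in 9 of 23 cases and higher in 3 (adjusted p = 1.29e-05). B cell sets were lower in 7 of 31 cases and higher in 5 (adjusted p = 0.00508). HADDAD_B_LYMPHOCYTE_PROGENITOR counts in and leads both of these themes, so their calls are not separate. The theme of WNT, NOTCH and hedgehog signalling had 8 of 53 sets lower and 8 higher, and only the lower direction was called (adjusted p = 0.0210). T and NK cell sets, which bear on cells left by CD3e depletion, had 3 of 21 higher and 4 lower, platelet and megakaryocyte sets 1 of 11 higher and 2 lower, and erythroid and heme sets 2 of 13 higher and 0 lower, none of them called by Fisher's exact test. Extracellular matrix and adhesion sets were higher in 0 of 37 cases and lower in 4, with fewer higher than among other sets (adjusted p = 0.00291). By median NES, extracellular matrix and adhesion (-1.25), T and NK cell (-1.32), platelet and megakaryocyte (-1.34), polycomb (-1.21) and monocyte, macrophage and dendritic cell sets (-1.20) also lay below random lists (adjusted permutation p from 0.0009 to 0.0432). Counting each source of sets once ended the calls for inflammatory signalling (adjusted p = 0.498, odds ratio 1.92 against 2.35), cell cycle (0.0700, 2.69 against 4.35), ribosome and translation (0.180, 7.85 against 28.3), hypoxia and glycolysis (0.0552, 3.88 against 3.31) and WNT, NOTCH and hedgehog (0.255, 4.10 against 3.48). Sets of 25 to 200 genes alone ended the calls for interferon (adjusted p = 0.357, odds ratio 2.35 against 5.36) and B cell (0.0599, odds ratio 4.24 against 5.72), stress and unfolded protein was lost at FDR q below 0.25 (0.0787, odds ratio 8.49 against 19.98) and by median NES against random lists (adjusted permutation p = 0.0605), as was WNT, NOTCH and hedgehog (0.214), and by the form of that p first used no call on the higher side was made (0.339 to 0.382).

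In bone marrow of YUMM3.3-bearing animals, ribosomal and mitochondrial respiration sets were higher than in healthy marrow. In all, 376 sets were higher and 253 lower. The authors' deposited table placed REACTOME_SRP_DEPENDENT_COTRANSLATIONAL_PROTEIN_TARGETING_TO_MEMBRANE first, with an NES of 3.23, then KEGG_RIBOSOME with 3.13. PECE_MAMMARY_STEM_CELL_UP had an NES of 3.05 in the authors' deposited table, KEGG_OXIDATIVE_PHOSPHORYLATION 2.95 and HSIAO_HOUSEKEEPING_GENES 2.81. Ribosome and translation sets were higher in 15 of 16 cases and lower in 0 (Fisher's exact test, adjusted p = 3.77e-13). Mitochondrial respiration had 9 of 20 sets higher and 0 lower (adjusted p = 0.00117), and WNT, NOTCH and hedgehog had 13 of 53 higher and 2 lower (adjusted p = 0.0221). No theme was called lower by Fisher's exact test. By median NES, however, cell cycle (-1.23), B cell (-1.14) and cholesterol and lipid (-1.24) lay below random lists (adjusted permutation p = 0.0018, 0.0252 and 0.0018). Polycomb (1.25) and complement and coagulation (1.49) lay above them (adjusted permutation p = 0.0162 and 0.0455), but not by the form of p first used (0.730 and 0.0761). The largest NES sizes on the lower side of the authors' deposited table belonged to DACOSTA_UV_RESPONSE_VIA_ERCC3_COMMON_DN, at 2.72, and DACOSTA_UV_RESPONSE_VIA_ERCC3_XPCS_DN, at 2.63, followed by GABRIELY_MIR21_TARGETS, at 2.59. ZHENG_FOXP3_TARGETS_IN_THYMUS_UP had an NES size of 2.49 in the authors' deposited table and SENESE_HDAC1_TARGETS_UP 2.40. Cell cycle sets were higher in 15 of 84 cases and lower in 11, with neither direction called by Fisher's exact test. B cell sets were higher in 4 of 31 cases and lower in 5, and T and NK cell sets higher in 2 of 21 and lower in 1. With each source counted once, mitochondrial respiration (adjusted p = 0.0984, odds ratio 11.5 against 7.79) and WNT, NOTCH and hedgehog (1.00, 1.31 against 3.10) were no longer called. The latter call was also lost at FDR q below 0.25 (adjusted p = 0.440), with DN sets kept (0.0596) and by median NES against random lists (adjusted permutation p = 0.423), and by the form of that p first used both were lost (0.730).

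Between the tumours, bone marrow of B16F10-bearing animals had higher cell cycle sets and lower ribosomal and polycomb sets than that of YUMM3.3-bearing animals. There were 314 sets higher and 326 lower with B16F10. The authors' deposited table gave IVANOVA_HEMATOPOIESIS_MATURE_CELL an NES of 2.55 toward B16F10, DACOSTA_UV_RESPONSE_VIA_ERCC3_COMMON_DN 2.49 and FISCHER_G2_M_CELL_CYCLE 2.41. Toward YUMM3.3, the signal recognition particle set named above had an NES size of 3.26 in the authors' deposited table, KEGG_RIBOSOME 3.20 and REACTOME_RESPIRATORY_ELECTRON_TRANSPORT 2.83. REACTOME_PRC2_METHYLATES_HISTONES_AND_DNA, named for the complex that methylates histone H3 at lysine 27, had an NES size of 2.67 toward YUMM3.3 in the authors' deposited table. Which of its genes carried this score could not be seen without member genes. Cell cycle sets were higher with B16F10 in 26 of 84 cases and lower in 8 (Fisher's exact test, adjusted p = 1.84e-08), a call not made by median NES with the form of random-list p first used (adjusted permutation p = 0.751). Ribosome and translation sets were lower in 15 of 16 cases and higher in 0 (adjusted p = 4.30e-14). Mitochondrial respiration sets were lower in 9 of 20 cases and higher in 0 (adjusted p = 0.000244), but their median NES of -0.22 did not differ from random lists (adjusted permutation p = 0.841). The polycomb theme had 8 of 28 sets lower and 1 higher (adjusted p = 0.0213), and this call ended with each source counted once (adjusted p = 0.177, odds ratio 7.57 against 4.45) and with sets of 25 to 200 genes (1.00, 1.59).

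In spleen of B16F10-bearing animals, cell cycle, interferon, mitochondrial and MYC sets were higher than in healthy spleen, and B cell sets were lower. There were 643 sets higher and 62 lower. ROSTY_CERVICAL_CANCER_PROLIFERATION_CLUSTER led the authors' deposited table with an NES of 2.94, followed by SOTIRIOU_BREAST_CANCER_GRADE_1_VS_3_UP with 2.91. KONG_E2F3_TARGETS, targets of a transcription factor of cell cycle entry, had an NES of 2.84 in the authors' deposited table, and IVANOVA_HEMATOPOIESIS_MATURE_CELL 2.75. Cell cycle sets were higher in 55 of 84 cases and lower in 1 (Fisher's exact test, adjusted p = 2.08e-22). Interferon sets were higher in 13 of 21 cases and lower in 0 (adjusted p = 6.30e-05), led by HECKER_IFNB1_TARGETS with an NES of 2.11 in the authors' deposited table. Mitochondrial respiration had 10 of 20 sets higher and 1 lower (adjusted p = 0.00590), and MYC had 12 of 32 higher and 0 lower (adjusted p = 0.0314). On the lower side, the authors' deposited table listed REACTOME_DIGESTION_AND_ABSORPTION with an NES size of 2.56, KEGG_T_CELL_RECEPTOR_SIGNALING_PATHWAY with 2.37 and KEGG_B_CELL_RECEPTOR_SIGNALING_PATHWAY with 2.25. B cell sets were lower in 6 of 31 cases and higher in 2 (adjusted p = 9.44e-05). T and NK cell sets were lower in 6 of 21 cases and higher in 2 (adjusted p = 1.58e-05), although their median NES, 0.95, lay on the higher side. Erythroid and heme sets were higher in 4 of 13 cases and lower in 0, which was not called. DNA repair sets were higher in 10 of 35 cases and lower in 0, also not called. Their median NES of 1.46 lay above random lists (random median 1.11, adjusted permutation p = 0.0147). Counting each source once ended the calls for mitochondrial respiration (adjusted p = 0.615, odds ratio 3.84 against 5.10) and MYC (0.251, 2.84 against 3.06), and sets of 25 to 200 genes ended the MYC call (0.129, 2.86). The T and NK cell median did not differ from random lists (adjusted permutation p = 0.213), nor did that of mitochondrial respiration by the form of p first used (0.0507).

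In spleen of YUMM3.3-bearing animals, cell cycle, DNA repair, stress and interferon sets were higher than in healthy spleen, and platelet, complement and adhesion sets were lower. There were 607 sets higher and 206 lower. The authors' deposited table listed ROSTY_CERVICAL_CANCER_PROLIFERATION_CLUSTER with an NES of 3.55, GOBERT_OLIGODENDROCYTE_DIFFERENTIATION_UP with 3.49 and KONG_E2F3_TARGETS with 3.37. KAUFFMANN_DNA_REPAIR_GENES had an NES of 2.67 in the authors' deposited table and REACTOME_REGULATION_OF_HSF1_MEDIATED_HEAT_SHOCK_RESPONSE 2.42. Cell cycle sets were higher in 60 of 84 cases and lower in 1 (Fisher's exact test, adjusted p = 3.06e-29). DNA repair had 26 of 35 sets higher and 0 lower (adjusted p = 3.26e-13), stress and unfolded protein 5 of 6 higher and 0 lower (adjusted p = 0.00433), and interferon 9 of 21 higher and 0 lower (adjusted p = 0.0169). The interferon theme was led in the authors' deposited table by REACTOME_ANTIVIRAL_MECHANISM_BY_IFN_STIMULATED_GENES, with an NES of 2.38. Without member genes, the genes shared between the leading sets of these themes could not be counted, so these calls may not be separate. Toward healthy spleen, the authors' deposited table gave PICCALUGA_ANGIOIMMUNOBLASTIC_LYMPHOMA_UP an NES size of 2.61, RAGHAVACHARI_PLATELET_SPECIFIC_GENES 2.51 and REACTOME_COMPLEMENT_CASCADE 1.95. Platelet and megakaryocyte sets were lower in 5 of 11 cases and higher in 1 (adjusted p = 0.00192), and complement and coagulation sets were lower in 4 of 6 cases and higher in 0 (adjusted p = 0.00191). Extracellular matrix and adhesion had 7 of 37 sets lower and 0 higher (adjusted p = 0.0169). B cell sets were higher in 4 of 31 cases and lower in 2, T and NK cell sets higher in 2 of 21 and lower in 1, and erythroid and heme sets higher in 3 of 13 and lower in 1, none of them called. MYC sets, higher in 11 of 32 cases and lower in 2, were not called either (Fisher's exact test, adjusted p = 0.0603). Their median NES of 1.30 lay above random lists by either form of p (random median -0.134, adjusted permutation p = 0.0054). Counting each source once ended the calls for interferon (adjusted p = 0.165, odds ratio 4.96 against 4.09) and for extracellular matrix and adhesion (1.00, 1.91 against 4.28). So did sets of 25 to 200 genes alone (adjusted p = 0.134, odds ratio 3.299, and 0.0879, odds ratio 4.07), and by the form of random-list p first used the calls for platelet and megakaryocyte and for extracellular matrix and adhesion were not made (adjusted permutation p = 0.630 for each).

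Between the tumours in spleen, B16F10-bearing animals had higher interferon, mitochondrial and coagulation sets than YUMM3.3-bearing animals, and a larger share of B cell sets than of other sets was lower. There were 374 sets higher and 57 lower with B16F10. The authors' deposited table gave IVANOVA_HEMATOPOIESIS_MATURE_CELL an NES of 2.88, CHYLA_CBFA2T3_TARGETS_DN 2.83 and BROWN_MYELOID_CELL_DEVELOPMENT_UP 2.38. WELCH_GATA1_TARGETS, targets of an erythroid and megakaryocyte transcription factor, had an NES of 2.34 in the authors' deposited table. Toward YUMM3.3, REACTOME_REGULATION_OF_CHOLESTEROL_BIOSYNTHESIS_BY_SREBP_SREBF had the largest NES size in the authors' deposited table, 2.51, and MORI_PLASMA_CELL_DN had 2.29. Interferon sets were higher with B16F10 in 7 of 21 cases and lower in 0 (Fisher's exact test, adjusted p = 0.0345). Mitochondrial respiration had 8 of 20 sets higher and 1 lower (adjusted p = 0.00826), and complement and coagulation had 4 of 6 higher and 0 lower (adjusted p = 0.0195). B cell sets were lower in 5 of 31 cases and higher in 0 (adjusted p = 0.00391), with a median NES of 0.75 on the other side. Platelet and megakaryocyte sets were higher in 4 of 11 cases and lower in 0, and erythroid and heme sets higher in 3 of 13 and lower in 0, neither of them called by Fisher's exact test. The platelet and megakaryocyte median of 1.62 lay above random lists (random median 1.08, adjusted permutation p = 0.0119), but not by the form of p first used (0.121). The DNA repair median of -0.94 lay below them by either form (0.0054). The mitochondrial call was lost with each source counted once (adjusted p = 0.802, odds ratio 3.60 against 6.37) and at FDR q below 0.25 (0.0826, 3.10), and the interferon call with sets of 25 to 200 genes (0.138, 4.20 against 4.76). The B cell median did not differ from random lists (adjusted permutation p = 0.0894), and by the form of that p first used interferon (0.0724), mitochondrial respiration (0.121) and complement and coagulation (0.537) did not either.

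In culture, YUMM3.3 had higher extracellular matrix, adhesion and TGF-beta sets than B16F10, and B16F10 had higher mitochondrial respiration and interferon sets. There were 458 sets higher in YUMM3.3 and 57 lower. The authors' deposited table gave NABA_CORE_MATRISOME, the structural proteins of the extracellular matrix, an NES of 2.32 and KEGG_ECM_RECEPTOR_INTERACTION 2.24. PLASARI_TGFB1_TARGETS_10HR_UP had an NES of 2.22 in the authors' deposited table and ANASTASSIOU_MULTICANCER_INVASIVENESS_SIGNATURE 2.24. Extracellular matrix and adhesion sets were higher in 28 of 37 cases and lower in 0 (Fisher's exact test, adjusted p = 1.26e-17). TGF-beta had 14 of 28 sets higher and 0 lower (adjusted p = 9.77e-06). Toward B16F10, the authors' deposited table listed KEGG_OXIDATIVE_PHOSPHORYLATION with an NES size of 2.30, SANA_RESPONSE_TO_IFNG_UP with 2.22, REACTOME_IRON_UPTAKE_AND_TRANSPORT with 2.12 and KEGG_LYSOSOME with 2.09. Mitochondrial respiration sets were lower in YUMM3.3 in 9 of 20 cases and higher in 0 (adjusted p = 6.76e-11), and interferon sets were lower in 8 of 20 cases and higher in 0 (adjusted p = 2.63e-09). These theme calls were made under every alternative fixed before the data were examined that gave a value. The sample titles of the lines carry different prefixes with none in common, so a batch that these prefixes might mark cannot be told apart from the line.

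**Figure D2:**
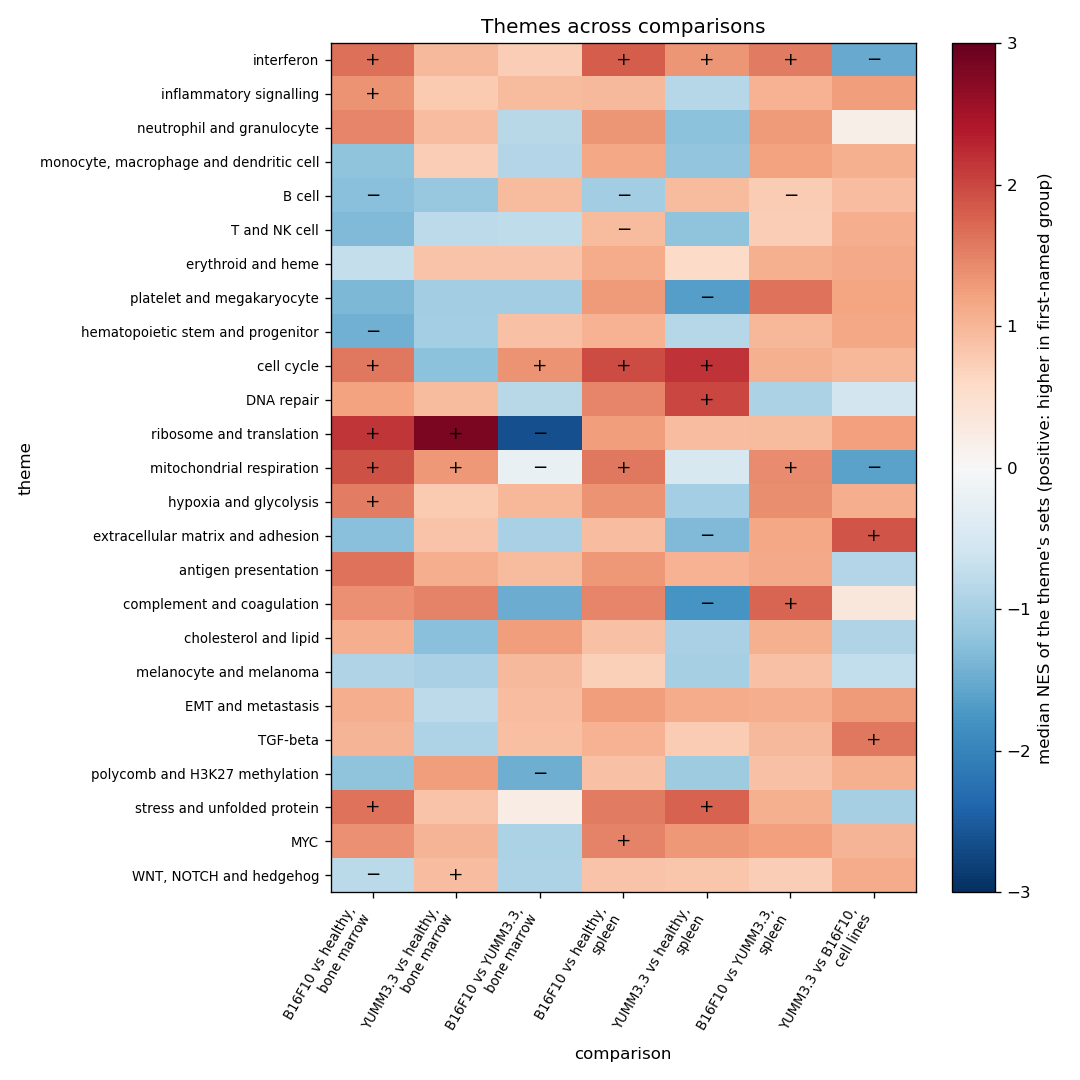
Median NES of the sets of each of 25 tested themes (rows) in the 7 comparisons (columns), positive where higher in the first-named group, with a plus or minus sign where the theme was called higher or lower. Ribosome and translation stands at 2.83 in YUMM3.3-bearing against healthy bone marrow and at -2.64 in B16F10 against YUMM3.3 bone marrow.

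Set by set, the tumours' NES against healthy correlated with r = 0.246 (rho = 0.264) in bone marrow and r = 0.276 (rho = 0.306) in spleen, across 3883 gene sets that are not independent. Unchanged libraries sharing the healthy controls gave a simulated r of 0.319 in bone marrow (range 0.245 to 0.368) and 0.373 in spleen (range 0.334 to 0.416), so neither observed value exceeded the simulated mean. The simulation used independent genes, random sets and no tumour effect. An r below the simulated one therefore cannot tell whether the tumours agree beyond their shared controls. The share of sets with the same sign was also below the simulated one, at 58.6% against 62.7% in bone marrow and 55.7% against 65.5% in spleen. The covariance lay above it, at 0.459 against 0.334 in bone marrow and 0.457 against 0.391 in spleen. Covariance also grows with the spread of NES. With r below the simulated mean, the higher covariance reflects a wider spread of NES than in the simulation and does not show more agreement. In spleen, 343 sets were higher with both tumours and 6 lower with both, and in bone marrow 218 and 17. No expected overlap under shared controls was computed, so all of this overlap may come from the shared healthy libraries, which could not be split.

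Across tissues, which share no library, B16F10-bearing animals had r = 0.558 (rho = 0.640) between bone marrow and spleen, and YUMM3.3-bearing animals r = -0.170 (rho = -0.185), again across sets that are not independent. A joint reversal of a single tissue's comparisons, which cannot be excluded, would turn the sign of both correlations. It would also change the overlaps and theme differences between tissues. With B16F10, 396 sets were higher in both tissues against 129.3 for independent lists, and 27 were lower in both against 3.10. With YUMM3.3, 97 were higher in both against 58.8, and 101 were lower in marrow but higher in spleen against 39.5. For canonical pathways alone, the YUMM3.3 correlation was 0.0530, on the other side of 0. Of 27 themes, 8 differed between tissues with B16F10 and 7 with YUMM3.3 (permutation test against random lists of sets). The cell cycle theme with YUMM3.3 had a mean NES of 1.73 in spleen and -0.279 in marrow (adjusted permutation p = 0.0012), and ribosome and translation had 0.237 in spleen and 2.72 in marrow (adjusted permutation p = 0.0012).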

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

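The tests of single sources and of gene length in YUMM3.3-bearing marrow, of erythroid cells with B16F10 and of lymphocytes were chosen only after the results they address had been seen, while the tests of gene length in B16F10-bearing marrow and of erythroid cells in YUMM3.3-bearing spleen were set out before theirs. The form of the two-sided p was changed after all of these had first been computed.

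The following themes differed between tissues by a test of the difference itself, as mean NES against healthy in spleen minus bone marrow, set beside random lists of sets. With B16F10, the themes above their random lists were platelet and megakaryocyte, at 1.77, polycomb and H3K27 methylation, at 1.29, extracellular matrix and adhesion, at 1.21, and erythroid and heme, at 1.16. Those below were ribosome and translation, at -0.616, mitochondrial respiration, at -0.610, and inflammatory signalling, at -0.187 beside a random median of 0.412. With YUMM3.3, the themes above were cell cycle, at 2.01, and DNA repair, at 1.28. Those below were complement and coagulation, at -3.18, ribosome and translation, at -2.48, polycomb and H3K27 methylation, at -1.52, and extracellular matrix and adhesion, at -1.45. Adjusted permutation p ranged from 0.0012 to 0.0475 (erythroid and heme), and these tests compare gene sets and not animals. They also rest on the reading of directions in both tissues.

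Ribosome and translation sets were higher in marrow of both tumours than in healthy marrow. For YUMM3.3 the theme was still called with each source counted once (4 of 5 sets, Fisher's exact test, adjusted p = 0.00139). This limits repeated counting of 1 source but cannot exclude it. REACTOME has sets in different combinations of themes and so entered the 5 more than once, and sources share ribosomal genes. For B16F10 the same count ended the call (adjusted p = 0.180, odds ratio 7.85 against 28.3), so repeated counting stays open there. A trend with gene length stays open as a candidate explanation: the 12 sets lowered after UV light, which are known for long genes, had a median NES of -1.83 against a random median of 0.0947 (permutation p = 0.0002, the smallest the lists can give), but some of these sets had been noticed in the same comparison. For B16F10 their median was -1.17 (random median 0.944, permutation p = 0.0588, or 0.0294 by the earlier form of p), which decides nothing. Between the tumours, DACOSTA_UV_RESPONSE_VIA_ERCC3_COMMON_DN had a deposited NES size of 2.49 toward B16F10 in marrow and 2.22 toward YUMM3.3 in spleen. A trend with gene length was not tested in those comparisons. Gene lengths could not be tested without member genes, 1 of the 2 YUMM3.3 libraries could carry the pattern unseen, and a response of the marrow to the tumour remains untested.

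Cell cycle sets were higher in spleen of both tumours. More erythroid cells among the isolated cells might bring such sets, since depletion of CD3e-positive cells does not remove them. The 13 erythroid and heme sets had a median NES of 1.11 with B16F10 (random median 1.05, permutation p = 0.741) and 0.57 with YUMM3.3 (random median -0.701, permutation p = 0.803). By counts, 4 were higher and 0 lower with B16F10, and 3 higher and 1 lower with YUMM3.3, neither called. With B16F10 their mean NES was 1.16 higher in spleen than in marrow (random median 0.313, adjusted permutation p = 0.0475). Between the tumours in spleen, WELCH_GATA1_TARGETS, 1 of these 13 sets, had a deposited NES of 2.34 toward B16F10. The median of the 13 sets in that comparison was 1.06 (random median 1.00, adjusted permutation p = 0.929). More erythroid cells and proliferation of the myeloid cells cannot be told apart, with set medians too scattered to decide and no single genes.

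B cell sets were lower in spleen with B16F10, and a smaller share of lymphocytes of every kind may account for it. The 21 T and NK cell sets had a median NES of 0.951 (random median 1.18, permutation p = 0.0940), with 11 above 0 and 10 below. The same sets were nevertheless called lower by Fisher's exact test, in 6 of 21 cases (odds ratio 27.2, adjusted p = 1.58e-05). CD3e depletion removes T cells before sequencing, which weakens T cell sets as a test of lymphocyte share. That explanation and a change within B cells both stay open, and other changes in the mix of isolated cells were not tested.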

How the results depend on the processing

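The alternatives were chosen before the data were examined, but without fixing the form of the two-sided p for random lists. That p was first taken by distance from the random median. The doubled smaller tail now in use was chosen after seeing the data, and so was keeping the earlier form as an alternative. Counts of sets are given as higher, then lower, in the first-named group. At FDR q below 0.25 they were 1442 and 674 for B16F10 against healthy marrow, 774 and 781 for YUMM3.3 against healthy marrow, and 828 and 695 for B16F10 against YUMM3.3 marrow. In spleen they were 1347 and 225 for B16F10, 903 and 969 for YUMM3.3, and 1103 and 198 between tumours, and the cell lines gave 1372 and 144. At FDR q below 0.01 the same comparisons gave, in marrow, 429 and 82, 235 and 86, and 121 and 181. In spleen they gave 404 and 31, 449 and 49, and 144 and 28, and in the lines 197 and 22. By FWER p below 0.05 the counts were 187 and 33, 126 and 35, and 47 and 84 in marrow, then 204 and 19, 266 and 13, and 55 and 15 in spleen, and 79 and 14 in the lines. Canonical pathways, which are fewer sets, left 267 and 57, 199 and 110, and 127 and 189 in marrow, then 156 and 40, 239 and 57, and 54 and 26 in spleen, and 90 and 25 in the lines. With sets of 25 to 200 genes, all 14 counts stayed within 1.5 times the main ones.

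Themes called in YUMM3.3 against healthy marrow numbered 6 at FDR q below 0.25, 7 by median NES against random lists and 1 with each source counted once, against 3. In B16F10 against YUMM3.3 marrow they numbered 7 at FDR q below 0.25, against 4. B16F10 against healthy marrow had 4 with each source counted once, against 10. YUMM3.3 against healthy spleen had 2 that way and 3 with sets of 25 to 200 genes, against 7. Between tumours in spleen there were 2 with each source counted once, 2 with sets of 25 to 200 genes and 7 by median NES, against 4. The cell lines had 8 by median NES, against 5. The earlier form of p gave 2 by median NES in B16F10 against YUMM3.3 marrow and 2 in spleen. It ended 20 of the 39 theme calls, among them all those on the higher side in B16F10 against healthy marrow (adjusted p = 0.339 for cell cycle and 0.382 for each other). The cause of these moves was not tested. Of 39 theme calls, 19 were made under all alternatives fixed beforehand that gave a value, with the p now in use, and 15 of them also by the earlier form. No call reversed. Counting each source once lost 13 calls and sets of 25 to 200 genes lost 7. Both gave no value for themes left with under 5 sets. For the size limits these were, among called themes, complement and coagulation and stress and unfolded protein. The YUMM3.3 correlation between tissues reversed for canonical pathways alone, from -0.170 to 0.0530, and the spleen correlation between tumours moved to 0.382 there. The cause was not tested. The number of themes that differed between tissues stayed within 1.5 times under every alternative, and erythroid and heme with B16F10 was lost with unmatched lists (adjusted p = 0.108).

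Leaving out replicates, other splits of the samples and any weighting by depth were not run, because the values analysed are 1 per gene set and comparison. No paired analysis was possible because no value belongs to a single library.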

Other observations

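Several themes were called in no comparison by Fisher's exact test. By median NES against random lists, cholesterol and lipid lay lower in YUMM3.3-bearing than in healthy marrow (adjusted permutation p = 0.0018), higher in B16F10-bearing than in YUMM3.3-bearing marrow (0.0027, but 0.751 by the earlier form of p) and lower in the YUMM3.3 line (0.0018). Monocyte, macrophage and dendritic cell sets lay lower in B16F10-bearing than in healthy marrow that way (0.0432), although by counts 4 of 15 were higher there and 2 lower, and EMT and metastasis higher in YUMM3.3-bearing than in healthy spleen (0.0194). By counts, neutrophil and granulocyte sets were higher in B16F10-bearing than in healthy marrow in 3 of 6 cases and lower in 1, and antigen presentation sets were higher in 4 of 7 and lower in 1. Sets for monocytes, macrophages and dendritic cells were higher in 5 of 15 cases in B16F10-bearing against YUMM3.3-bearing spleen and lower in 0. Cholesterol and lipid sets were lower there in 3 of 33 cases and higher in 1, and the SREBP set named above was among the largest in that direction. Sets for EMT and metastasis were higher in the YUMM3.3 line in 12 of 46 cases and lower in 0. The melanocyte and melanoma theme had 0 of 5 sets past the threshold in either direction between the lines, too few sets to tell from the share of other sets past it (11.8% higher and 1.47% lower).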
